A study of Mus musculus with 2 samples.

How the data were processed

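The series holds 2 arrays, 1 of wild type 46C mouse embryonic stem cells and 1 of 46C cells labelled as a Linc1548 knockout, both at day 5 of neural differentiation. Groups were taken from the genotype in the labels. Per the labels, total RNA was labelled with Cy3 after linear amplification and hybridised as a one-colour experiment. Per the labels' protocols, RNA was extracted with Trizol; that text describes ground tissue although the samples are cultured cells, so its details were not relied on.

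The files are the output of Agilent Feature Extraction 10.7.1.1, per the file headers, and hold spot intensity values with no normalization between arrays. Per the file headers, the processed intensity was background-subtracted and corrected for spatial and multiplicative trends within each array, and signals too low to measure were replaced by a surrogate value. The mean spot intensity and the local background intensity, deposited beside it, served only for the alternative background correction. Probe positions in the files are on mouse build mm9. The headers place both arrays on the same slide and in the same scan, so neither separates the groups, while array position and culture coincide with the group.

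Each array has 62976 spots, of which 59305 are not controls, for 56605 probes; 300 of these are printed in 10 spots each. Outlier spots were left out (173 on the wild type array and 155 on the knockout array) and spots of a probe were averaged on the log2 scale. Log2 processed signals were centred on each array's 75th percentile over non-control probes, which was 864 on the wild type array and 652 on the knockout array before centring. Signals in the text are scaled to a common 75th percentile. A probe counted as measured where, on both arrays, the software called a share of at least 0.5 of its spots well above background and the probe was not saturated, which left 31536 probes. The value of a gene is the median of the log2 differences of its measured probes, and its fold is the power of 2 of that difference. Signals are printed only for genes with 1 probe, since the median signals of several probes need not give the median difference. Of 7055 genes with several probes, 875 had probes whose log2 differences spanned over 1, and 22 had probes at least 2-fold in both directions.

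Gene names were updated through a RefSeq table of assembly GRCm38.p6, used for names only. The accession matched for 32994 probes, the symbol for 10224 and a synonym for 520; 8418 probes kept the name of the array design, and 4449 probes are named by the coordinates of a long intergenic RNA locus. The latter were counted apart from genes. In all, 32947 gene names are on the array and 18671 genes were measured on both arrays, 15470 of them named by the RefSeq table.

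With 1 array per group, no test was run and no p-value is given. A fixed limit of 2-fold was applied, and probes printed in several spots show what spot noise allows. Over 298 such probes the pooled SD of log2 signal between spots was 0.064 on the wild type array and 0.068 on the knockout array, and 0 of 11093 pairs of spots of the same probe differed 2-fold on either array. This is error within an array and says nothing of the spread between cultures. The number of arrays limits the precision. For a gene measured on a single array, the fold is a lower bound: its signal there against the higher of the lowest signal well above background on the other array and the probe's own signal on that array.

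There were 37 gene lists, written before the data were examined, as were the design, the rule for named genes and the alternatives other than those said to be added. For each list the median log2 difference was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and a list was called outside where its median left the central 95%. Of the 37 lists, 22 were outside, 12 above and 10 below. A rate of 1 list in 20 holds for lists of genes drawn at random. Genes of a marker list can vary together between any 2 cultures, so more lists than that can fall outside without an effect of genotype. Several lists also share genes. The text names Pou3f1 and Sox2, the 15 largest differences each way with 3 predicted genes each way, the 5 largest bounds each way, and the 2 highest and 2 lowest members of lists outside the central range; a gene named beyond this rule is said to be so. Some genes that the rule takes are not reported here, though lists and counts include them.

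The steps were tested on simulated arrays made from the real signals with the measured spot noise. Of 200 genes changed by 1.5 on the log2 scale among 18671, 200 were recovered with 0 unchanged genes called, and the same held for 200 genes changed by 2.5. Of 100 random lists of 20 unchanged genes, 4 fell outside the central range, and 100 of 100 lists raised by 0.5 lay above it. Unchanged genes in these simulations differed by spot noise alone (SD 0.093), whereas the measured gene differences had an SD of 0.98. The simulations therefore check the steps only. They do not give the power or the rate of false calls for differences between cultures.

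Alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), centring on the median, quantile normalization, loess on mean signal, centring on the E1A spike-in probes, no filter and a stricter filter on dim probes, the brightest probe per gene, keeping outlier spots, a log2 limit of 2, and another detection call for genes measured on a single array. Genes named by the RefSeq table alone and genes whose probes share a direction were added after the data were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Linc1548 itself was not analysed here, because 0 probes name it and no search by position was made.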

Results

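Total RNA from mouse 46C embryonic stem cells, a line that carries a GFP reporter at the Sox1 locus, was measured on one-colour microarrays at day 5 of neural differentiation, when the cells grew as floating aggregates in serum-replacement medium. There were 2 groups with 1 array each, wild type cells and cells labelled as a knockout of Linc1548, a long intergenic non-coding RNA. The comparison asks what the loss of this RNA does to the step from an epiblast-like state to neural progenitors. With 1 array per group there are no replicates, so no difference below has a replicate check and none was tested. Every direction is given for the knockout array relative to the wild type array.

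Of 56605 probes, 34757 (61.4%) lay well above background on the wild type array and 33133 (58.5%) on the knockout array. No probe was saturated. Across the 31536 probes measured on both arrays, log2 signals correlated with Pearson's r = 0.948; this correlation is across probes, which are not independent replicates. No probe on the array names Linc1548 (0 probes), and probe positions were not compared with its locus. A probe under another name is therefore not excluded. The level of the targeted RNA was not read, and the labels of the arrays were not checked against it. Both arrays lay on the same slide and were scanned together. In 3382 transcripts with probes at least 500 bases apart, the log2 difference of the probe nearer the 3' end lay below that of the probe nearer the 5' end by a median of −0.17 (95% bootstrap interval over transcripts −0.19 to −0.16). The arrays therefore also differed in signal along transcripts, though the probes compared were not matched on signal.

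At day 5, the knockout array showed higher signals for pluripotency, germ cell and 2-cell-like genes and lower signals for neural progenitor, neuronal and Notch pathway genes. Among 24 measured genes of naive pluripotency, 22 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 difference of 3.07. Among 32 neural progenitor genes, 24 were at least 2-fold lower and 3 were at least 2-fold higher, with a median of −2.0. Among 23 genes of neuronal differentiation, 19 were at least 2-fold lower and 0 were higher by that much, with a median of −2.46. Over 18671 genes measured on both arrays, 2149 (11.5%) were at least 2-fold higher and 1644 (8.81%) at least 2-fold lower.

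**Figure D1:**
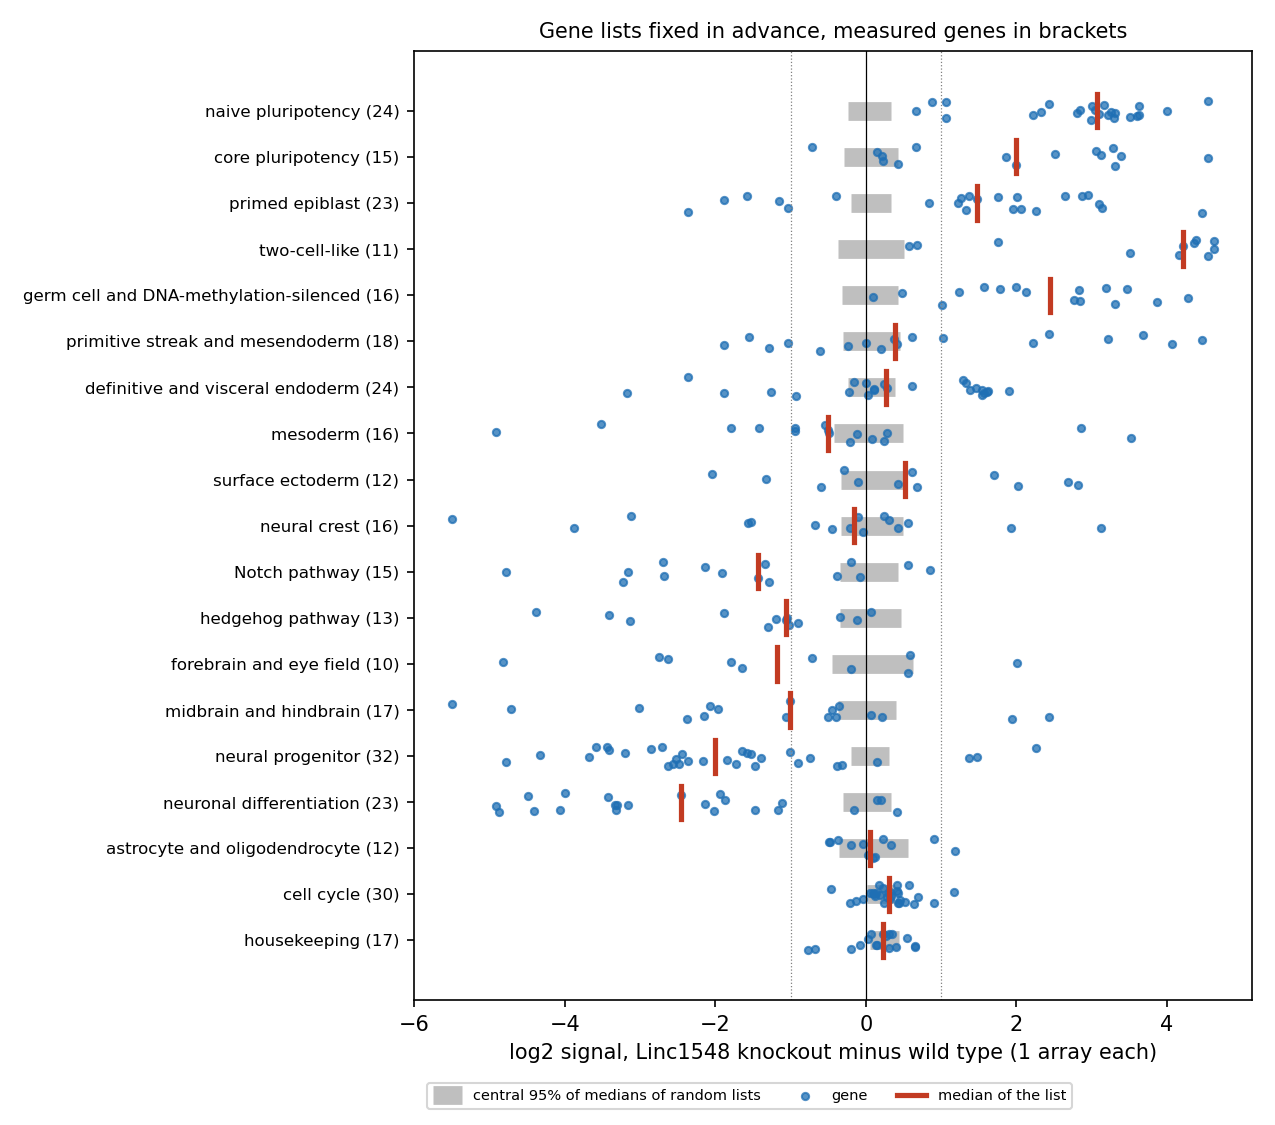
Log2 signal of the Linc1548 knockout array minus the wild type array (x axis, 1 array each) for genes of 19 lists fixed in advance (y axis, number of measured genes in brackets). Each blue point is 1 gene, the red bar is the list median and the grey band holds the central 95% of medians of 10000 random lists of the same size and similar signal; dotted lines mark 2-fold. The naive pluripotency median lies at 3.07 and the neuronal differentiation median at −2.46, both outside their bands, while the cell cycle median (0.31, or −0.08 when arrays are centred on spike-in controls) lies inside its own.

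The series title names 2 transcription factors. Pou3f1, which encodes OCT6, a POU factor of the epiblast and early neural cells, read 8648 on the knockout array against 3702 on the wild type array, a log2 difference of 1.22 (2.34-fold); with the arrays centred on spike-in controls the difference was 0.83, under the 2-fold limit. Its probe lies on chromosome 4 at 124337692 to 124337751 (mouse build mm9). Sox2, a factor shared by pluripotent cells and neural progenitors, read 15908 against 14336, a log2 difference of 0.15 that turned negative with quantile normalization (−0.06), loess (−0.04) and spike-in centring (−0.24). The Sox2 probe lies on chromosome 3 at 34551260 to 34551316 (mm9).

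Genes of the naive pluripotency list, chosen to mark embryonic stem cells before they enter the epiblast state, were higher almost throughout, as the plot of list members shows. The list median exceeded all 10000 random lists of the same size and similar signal; like every such percentile here, this describes these libraries. Tdgf1, the Nodal co-receptor, was 23.3-fold higher by the median of its 5 probes, whose log2 differences ran from 2.21 to 4.81. It is also on the core pluripotency list, so it is not particular to the naive state. Dppa2, a chromatin factor of pluripotent cells, was 16-fold higher. The smallest differences were those of Pecam1 (log2 0.87) and Nanog (0.66), and the Nanog value is uncertain because its probes disagreed, at 2.95 and −1.63. At least 1 Nanog probe shares 25 or more bases with a probe of Zfp872, and which one was not separated. Zfp42 (11.3-fold), Esrrb (9.95-fold) and Klf4 (7.93-fold) were further members, chosen for mention after their values were seen. Of 15 core pluripotency genes, 9 were at least 2-fold higher and 0 lower by that much (median 1.99, above all 10000 random lists). L1td1, an RNA-binding protein of embryonic stem cells, was 10.5-fold higher in this list and Lin28b was lower (log2 −0.71, or −1.10 and past 2-fold with spike-in centring). Pou5f1, which encodes OCT4 and was also picked after its value was seen, was 3.97-fold higher.

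Primed epiblast genes moved less uniformly. Of 23 measured, 16 were at least 2-fold higher and 5 at least 2-fold lower (median 1.48, above all 10000 random lists). Lefty2 (22.1-fold) and Lefty1 (8.80-fold), secreted antagonists and targets of Nodal signalling, were the highest. Sox3 (5.14-fold) and Foxa2 (3.68-fold) were the lowest; Sox3 is also a neural progenitor gene and Foxa2 a gene of the floor plate and of endoderm. Nodal (7.33-fold), Fgf5 (6.28-fold) and Dnmt3b (4.19-fold by the median of 3 probes), picked after their values were seen, were higher.

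Neural progenitor genes had a median below those of all 10000 random lists. Hes5, a Notch effector of neural progenitors, read 1538 on the knockout array against 42256 on the wild type array, 27.5-fold lower, and Nr2f1 (COUP-TFI) was 20.1-fold lower. The Hes5 probe lies on chromosome 4 at 154336361 to 154336420 (mm9). The member of this list that was highest in the knockout was Zic5 (4.8-fold by the median of 3 probes), a zinc finger gene that the epiblast also expresses. Pax6 was 12-fold lower with its probes at −3.64 and −3.53, Nes, the intermediate filament nestin, 5.73-fold lower, and Sox1 5.60-fold lower; these 3 were picked after their values were seen.

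Genes of neuronal differentiation lay lower still, again below all 10000 random lists. Isl1, a motor neuron factor, was 30.2-fold lower and Myt1, a zinc finger factor of new neurons, 29.4-fold lower. The members closest to the opposite direction were Pou4f1 (log2 0.42, with probes at −0.80 and 1.63, or −0.80 without the filter on dim probes) and Stmn2 (0.21, or −0.18 with spike-in centring). Dcx (21.2-fold), Dll1 (8.97-fold) and Tubb3 (3.83-fold), named after their values were seen, were lower. Neurod4, Neurog1, Neurog2, Neurog3 and St18 were well above background only on the wild type array, with lower bounds of 46.6-fold for St18, 12.2-fold for Neurod4 and 10.8-fold for Neurog2 but 1.73-fold for Neurog1 and 1.15-fold for Neurog3, under the 2-fold limit. Of 15 Notch pathway genes, 10 were at least 2-fold lower and 0 higher by that much (median −1.43, below all 10000 random lists). Lfng, a glycosyltransferase that modifies Notch, was 9.39-fold lower beside Hes5, whereas Rbpj (log2 0.85) and Jag2 (0.56) were the highest.

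**Figure D2:**
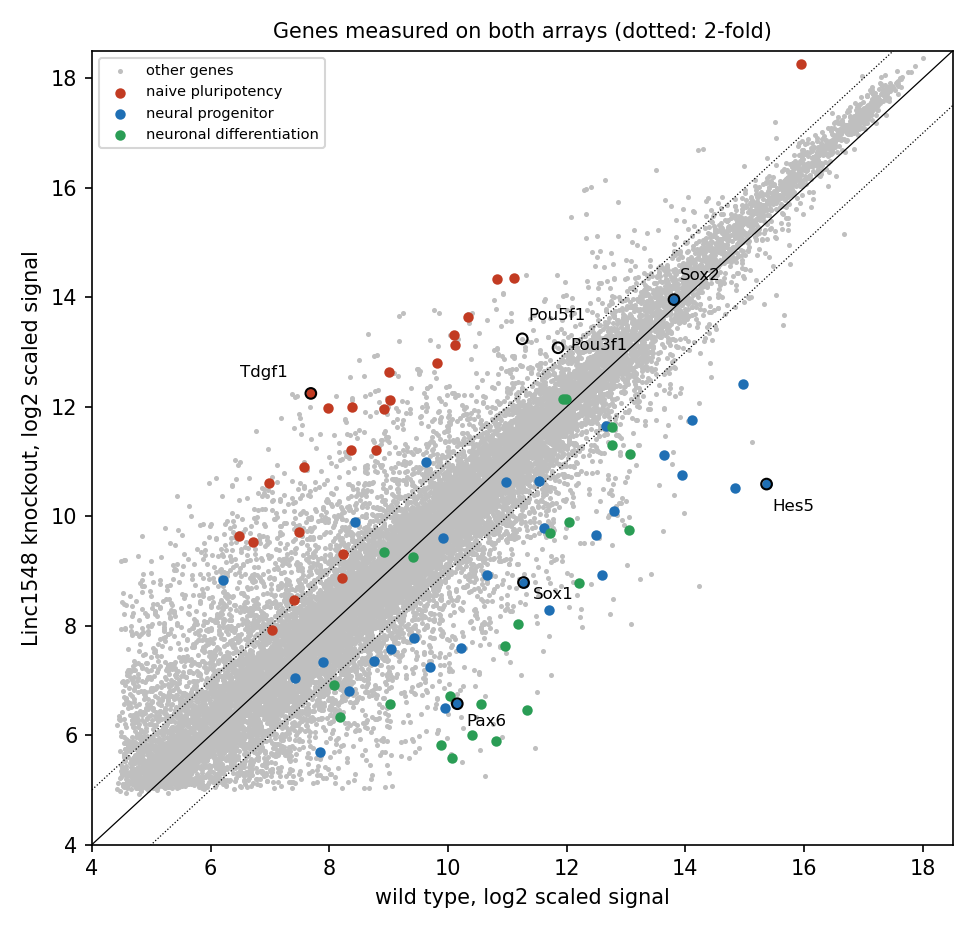
Scaled log2 signal on the wild type array (x axis) and on the Linc1548 knockout array (y axis) for 18671 genes measured on both, each point the median of a gene's probes on that array. The solid line marks equal signal and the dotted lines 2-fold; naive pluripotency genes (red) lie above the line, 22 of 24 of them at least 2-fold higher, and 24 of 32 neural progenitor genes (blue) and 19 of 23 neuronal genes (green) are at least 2-fold lower, by the median difference of each gene's probes.

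Regional markers of the nervous system were lower as lists. Of 17 midbrain and hindbrain genes, 9 were at least 2-fold lower and 2 at least 2-fold higher (median −1.0, below all 10000 random lists). Hoxa2, a hindbrain segment gene, was 26.2-fold lower, while Fgf8 (5.41-fold) and Pax8 (3.84-fold) were higher. Pax8 was within 2-fold (log2 0.25) when probes near background were kept, and this list's median moved to −0.50 with normexp background correction, −0.45 without the filter on dim probes and −1.96 with a stricter filter. Of 10 forebrain and eye field genes, 5 were at least 2-fold lower and 1 at least 2-fold higher (median −1.18, with 1 of 10000 random lists as low). Otx2 was 4.03-fold higher by the median of 3 probes and Six6 differed by 0.59. The median of that list was −0.53 with normexp and −2.21 with the stricter filter. A further 6 of its genes were well above background on the wild type array alone, among them Vax1 (at least 4.51-fold), Six3 (4.08-fold) and Fezf2 (2.88-fold), and, with bounds under 2-fold, Fezf1 (1.59-fold) and Nkx2-1 (1.16-fold).

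Genes of the hedgehog pathway and of the retinoic acid response, which pattern the neural tube, were lower as lists. In the hedgehog pathway 9 of 13 genes were at least 2-fold lower and 0 higher by that much (median −1.06, below all 10000 random lists). Nkx6-1, a ventral progenitor factor, was 20.8-fold lower and Hhip, a hedgehog target, 10.6-fold lower; Gli2 (log2 0.07, or −0.32 with spike-in centring) was at the upper end. Shh, the ligand of the pathway, was 8.78-fold lower and was picked after its value was seen. Nkx2-2 was well above background only on the wild type array, at least 21.7-fold higher there. Of 16 retinoic acid response genes, 6 were at least 2-fold lower and 2 at least 2-fold higher (median −0.55, with 16 of 10000 random lists as low, and −0.95 with spike-in centring). Hoxb1 (8.11-fold) and Cyp26b1 (6.08-fold) were the lowest, and Stra8 (19.5-fold) and Dhrs3 (4.65-fold) the highest; Stra8 is also a germ cell gene. The Hox list held both directions, with 5 of 18 genes at least 2-fold higher and 7 at least 2-fold lower. Its median of 0.21 lay inside the range of random lists and turned to −0.18 with spike-in centring and −1.03 with the stricter filter, and was 0.70 without the filter on dim probes. Among its members Hoxa2 and Hoxa3 (9.42-fold) were the lowest, and Hoxc9 (4.35-fold) and Hoxd4 (3.91-fold) the highest.

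Germ cell genes and 2-cell-like genes were higher. The 2-cell-like list holds genes of the 2-cell embryo that a small share of cultured embryonic stem cells also expresses. Of its 11 measured members, 9 were at least 2-fold higher and 0 lower by that much (median 4.21, above all 10000 random lists, and 3.41 with normexp). Gm8300 (24.8-fold) and Zscan4a (24.6-fold) were the highest, Eif1a (log2 0.68) and Zfp352 (0.58) the lowest, and Tcstv3, picked after its value was seen, was 17.9-fold higher. The wild type signal of Gm8300 (23.7) lay close to background, so its fold is uncertain. Probes of Zscan4a and Zscan4c share 53 of 60 bases, so those genes cannot be separated here. Zscan4 probes were compared with each other and not with transcripts, so signal from other Zscan4 genes is not excluded for any of them. Another 4 members were well above background only on the knockout array, Usp17lc by at least 21.0-fold, Tcstv1 by at least 3.55-fold, Zscan4d by at least 2.72-fold and Dux by at least 1.86-fold. Of 16 measured genes in a mixed list of germ cell genes and genes that DNA methylation silences, 14 were at least 2-fold higher and 0 lower by that much (median 2.45, above all 10000 random lists, and 1.79 with normexp). Stra8 and Tex19.1 (14.7-fold) were the highest, and Taf7l (log2 0.48) and Tuba3a (0.09, or −0.14 with quantile normalization, −0.11 with loess and −0.30 with spike-in centring) the lowest. Mael, a piRNA pathway gene picked after its value was seen, was 11.1-fold higher, and Dazl was well above background only on the knockout array, at least 14.0-fold.

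Markers of other lineages went both ways. Primitive streak and mesendoderm genes had 7 of 18 members at least 2-fold higher and 4 at least 2-fold lower (median 0.39, at percentile 95.2 of random lists, inside their central 95%, and 0.002 with spike-in centring); with normexp 6 were higher and 2 lower by that much. Cdx1 (16.8-fold) was the highest after Lefty2, and Foxa2 and Apln (2.92-fold) were the lowest. Of 16 mesoderm genes, 2 were at least 2-fold higher and 4 at least 2-fold lower; the median of −0.50 had 129 of 10000 random lists as low but turned to 0.08 with the stricter filter on dim probes, and was −0.89 with spike-in centring (6 genes at least 2-fold lower) and −0.20 with normexp (2 genes). Tcf15 (11.5-fold) and Bmp4 (7.26-fold) were its highest members, and Isl1 and Tbx20 (11.4-fold) its lowest. The knockout signal of Tbx20 (36.7) lay close to background, so its fold is uncertain. Parietal endoderm and basement membrane genes had 6 of 13 members at least 2-fold lower and 2 at least 2-fold higher (median −0.55, with 23 of 10000 random lists as low, −0.94 with spike-in centring, and −1.09 to −0.39 over all settings run). Plat (6.15-fold) and Pth1r (2.99-fold) were the lowest there, and Nid2 (3.20-fold) and Nid1 (2.18-fold, within 2-fold under 4 other settings, normexp and spike-in centring among them) the highest. Endothelium and blood genes had 5 of 14 members at least 2-fold higher and 1 at least 2-fold lower (median 0.64, with 96 of 10000 random lists as high, and 0.25 with spike-in centring, which left 2 genes at least 2-fold higher and 1 lower, against 4 higher in every other alternative scaling). Tek (4.30-fold) and Vwf (3.60-fold) were highest and Hba-x (2.25-fold, log2 −0.79 with normexp) and Hba-a1 (log2 −0.53, on probes that share bases with Hba-a2) lowest. The wild type signal of Tek (25.0) lay close to background, so its fold is uncertain.

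The medians of the other lineage lists lay inside the central 95% of random lists, and their size depended on the processing. The median was −0.16 for 16 neural crest genes (−0.55 to −0.04 over all settings run), 0.52 for 12 surface ectoderm genes (0.13 to 0.65) and 0.26 for 24 definitive and visceral endoderm genes (−0.13 to 0.61). It was −0.23 for 15 trophoblast genes (−0.62 to 0.39) and 0.35 for 13 cardiac and smooth muscle genes (−0.04 to 0.50). It was 0.12 for 16 fibroblast and matrix genes (−0.27 to 0.19) and 0.06 for 12 astrocyte and oligodendrocyte genes (−0.33 to 0.14). The lists whose range spans 0 therefore have no settled direction.

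Targets of growth factor pathways were divided. Of 21 BMP and TGF-beta target genes, 9 were at least 2-fold higher and 4 at least 2-fold lower (median 0.43, with 130 of 10000 random lists as high, 0.04 with spike-in centring and 0.97 with the stricter filter). Lefty2 and Lefty1 were the highest, and Id4 (3.11-fold) and Id3 (2.55-fold), targets of BMP signalling, the lowest. Of 17 FGF-ERK target genes, 5 were at least 2-fold higher and 0 lower by that much (median 0.73, with 2 of 10000 random lists as high, and 0.34 with spike-in centring, which put 3 genes at least 2-fold higher and 2 lower). Etv5 (7.29-fold) and Ier3 (4.14-fold) led this list, and Phlda1 (log2 −0.84) and Fgfr1 (−0.68, the median of 4 probes) were its lowest. Wnt target genes had 4 of 18 members at least 2-fold higher and 3 at least 2-fold lower (4 and 7 with spike-in centring), with a median of −0.29 (−0.68 to 0.14 over all settings run, so of no settled direction) inside the range of random lists.

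Housekeeping and growth genes differed little. Of 30 cell cycle genes, 29 were within 2-fold, the exception being Ccne1 (2.25-fold higher, and within 2-fold with quantile, loess and spike-in scaling), and the median was 0.31 (−0.08 with spike-in centring). All 26 ribosomal protein genes were within 2-fold in every scaling run. All 17 housekeeping genes were within 2-fold too, but with spike-in centring B2m (log2 −1.16) and Hprt (−1.06) were at least 2-fold lower, which left 15. Their medians of 0.36 and 0.23 lay inside the range of random lists and turned negative with quantile normalization (−0.02 and −0.08), loess (−0.05 and −0.07) and spike-in centring (−0.03 and −0.16).

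Outside the lists, the genes with the largest higher signals included Nphs1, which encodes nephrin (30.8-fold), Fam25c (26.8-fold), Hmox1, which encodes heme oxygenase (26.6-fold), Ct55 (25.2-fold), Cela2a (24.1-fold), Mymx, a myoblast fusion gene (22.4-fold), and Tslrn1 (20.2-fold). Fthl17e (29.1-fold) and Fthl17-ps1 (25.6-fold) were also among them, but their probes share 25 or more bases. With predicted genes ranked apart, the other genes of the 15 with the largest higher signals were Lefty2, Tdgf1, Zscan4a, Zscan4c (20.9-fold), Zscan4f (20.6-fold) and Usp17la (23.3-fold). Grb10, an imprinted adaptor of insulin receptor signalling, had the largest lower signal (52.4-fold, 54.1 against 2835). With predicted genes again ranked apart, the 15 largest lower signals also included Clvs1 (41.4-fold) and Insm1, a factor of neural and endocrine progenitors (33.2-fold). Wnt7a (31.0-fold), Ebf3 (25.1-fold), Vit (23.4-fold), Fgfr3 (22.9-fold), Ebf2 (22.4-fold) and Ly6h (22-fold) were among them too, as were Isl1, Myt1, Hes5 and Hoxa2. Among predicted genes, Gm38423 (27.7-fold), BY465212 (27.7-fold) and Gm29243 (25.9-fold) were the highest and 6430503K07Rik (26.3-fold), 2900092D14Rik (16.5-fold) and Gm2990 (13.4-fold) the lowest. Some of these folds rest on a signal close to background on the dimmer array and are uncertain. Examples are Ct55 (23.3) and Gm29243 (22.4) on the wild type array and Clvs1 (38.0) on the knockout array.

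Some genes were well above background on a single array, so that only a lower bound of the fold exists. There were 1589 such genes on the wild type array, 371 of them with a bound of at least 2-fold, and 954 on the knockout array, 703 of them with such a bound. After scaling, the lowest signal well above background was higher on the knockout array than on the wild type array. Bounds on the wild type side are therefore held lower, and the counts of the sides cannot be compared. The largest bounds on the wild type side were those of Ppp1r17 (at least 59.4-fold), St18 (at least 46.6-fold), Otp (at least 30.8-fold), Klhl35 (at least 22.8-fold) and Scg2 (at least 22.5-fold). On the knockout side they were those of Myo1f (at least 31.1-fold), Krt23 (at least 23.3-fold), Usp17lc (at least 21.0-fold), Entpd3 (at least 19.2-fold) and Fabp2 (at least 18.7-fold).

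The balance of the counts depended on how the arrays were scaled. Higher genes made up 56.7% of the genes differing by at least 2-fold in the scaling used throughout, and 31.8% with the arrays centred on spike-in controls, which put 1391 genes at least 2-fold higher and 2981 at least 2-fold lower. Spike-in centring lowers every log2 difference by the same 0.39, taking the median of all genes from 0.10 to −0.29, and so leaves the place of a list among random lists as it is. Normexp background correction put 1557 genes at least 2-fold higher and 1047 at least 2-fold lower. Without the filter on dim probes 4038 genes were at least 2-fold higher and 2587 at least 2-fold lower.

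**Figure D3:**
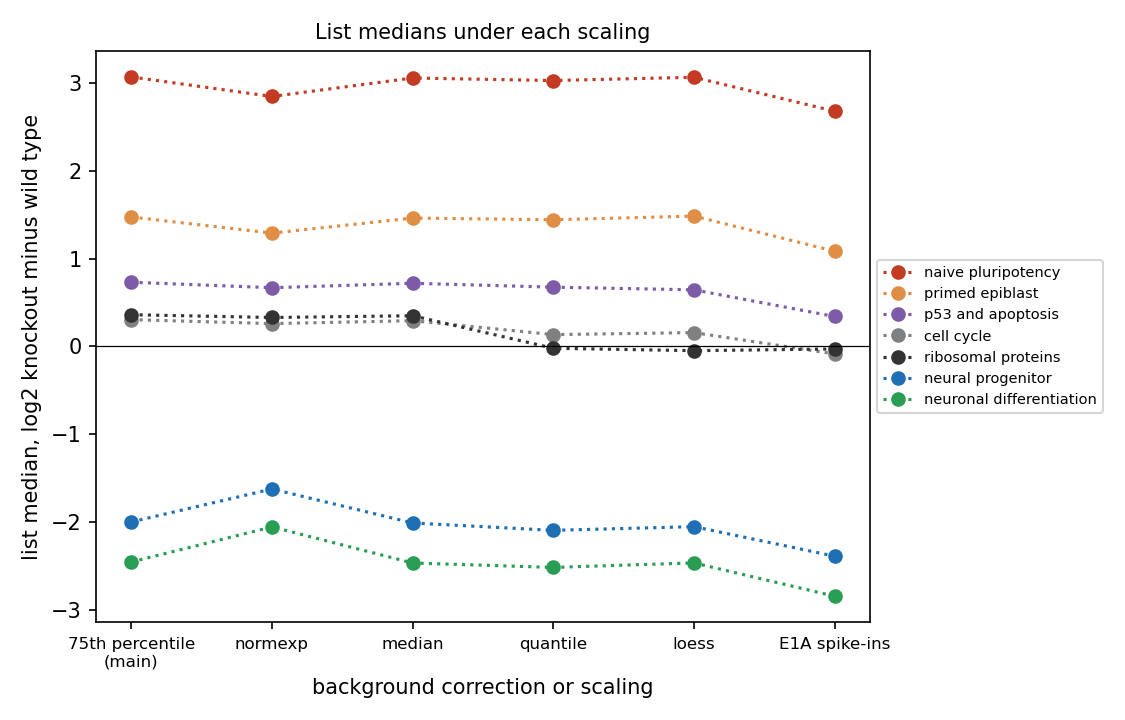
Median log2 difference, knockout minus wild type (y axis), of 7 gene lists under the scaling used throughout and 5 other background corrections or scalings (x axis). Dotted lines join the values of a list for reading only; the naive pluripotency median stays between 2.68 and 3.07 and the neural progenitor median between −2.39 and −1.63, whereas the ribosomal protein median (0.36 in the scaling used throughout) falls below 0 with quantile, loess and spike-in scaling and the cell cycle median with spike-in scaling.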

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

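The signal below was singled out after it was seen, and no explanation of it was tested. It comes from control probes that no comparison of the gene lists uses.

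Of 96 control probes for ERCC sequences, which are synthetic RNAs that can be added to samples, 2 were well above background in most of their spots on an array. The probe ERCC-00113_271 had a median processed signal of 93.6 over 28 spots on the knockout array (quartiles 66.2 and 114) and 31.5 on the wild type array (quartiles 17.1 and 36.5), 2.97 times as high on the knockout array. The probe ERCC-00148_99 read 57.3 and 51.2 on the same arrays. These signals are before scaling between arrays, and the labels do not say that ERCC RNA was added.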

How the results depend on the processing

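The settings that keep genes of the RefSeq table alone or genes whose probes share a direction were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason leaving out an array was not possible. The check of the targeted gene under other probe rules was not run, since no probe names it. The cause of the shifts below was not tested unless stated.

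With normexp, 1557 genes were at least 2-fold higher, against 2149, and 1047 at least 2-fold lower, against 1644. Spike-in centring gave 1391 higher and 2981 lower genes against 2149 and 1644, by construction, since it subtracts 0.39 from every difference; all 1391 were among the 2149, and the 2981 held all 1644. Keeping dim probes counts more genes and gave 4038 higher and 2587 lower ones. These held 2023 of the 2149 and 1489 of the 1644, and the median of all genes was 0.39 against 0.10. Added genes were therefore not the only change. A log2 limit of 2 gave 752 and 422. Under median, quantile and loess scaling, the stricter filter, the brightest probe, kept outlier spots and the added settings, both counts stayed within 1.5 times, as did the numbers of genes measured on a single array in each setting run for them.

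The naive pluripotency median was 2.85 with normexp and 2.68 with spike-ins. The primed epiblast median was 1.29 with normexp, 1.09 with spike-ins and 1.64 with the brightest probe. The neural progenitor median was −1.63 with normexp, −2.10 with quantile scaling, −2.39 with spike-ins, −2.17 with the brightest probe and −2.26 where probes share a direction. The neuronal differentiation median was −2.06 with normexp, −2.85 with spike-ins, −2.31 with dim probes kept and −3.23 where probes share a direction. The rule that probes share a direction drops genes whose probes lie on both sides of 0, which here lie above both medians, so it lowers these medians by construction and says nothing of their stability. Each median kept its sign in every other setting run. Of the lists called outside the random range, the mesoderm median alone reversed, to 0.083 with the stricter filter. Of the other values of list medians, 117 moved by more than the spot noise and 289 did not. Of the values of named genes, 445 moved, 1503 did not, and none of the genes past 2-fold changed sign. Spike-in centring subtracts 0.39 from every one of these values, so it adds to both moved counts by construction. Signal over background limits the dim genes: 58.5% of probes on the knockout array were well above it.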

Other observations

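The tests of scaling, intensity trend, near-identical family members, signal near background and labelling input were chosen after the results they bear on were seen; the tests of swapped labels and RNA degradation were set before.

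Imprinted genes, interferon response genes and metabolic genes also differed. Of 25 imprinted genes, 9 were at least 2-fold lower and 4 at least 2-fold higher (median −0.48, with 1 of 10000 random lists as low, and −0.87 with spike-in centring). Grb10 (52.4-fold) and Igf2 (13.0-fold) were the lowest, while H19, the non-coding neighbour of Igf2, was 11.5-fold higher and Phlda2 5.80-fold higher. Of 17 interferon response genes, 9 were at least 2-fold higher and 0 lower by that much (median 1.26, above all 10000 random lists), led by Oasl2 (15.0-fold) and Oas1a (7.70-fold). The wild type signal of Oasl2 (25.0) lay close to background, so its fold is uncertain. Ifit2 (log2 −0.97) and Usp18 (−0.87), which the same response induces, were lower. With spike-in centring 3 genes of the list passed 2-fold lower, and 1 did with quantile or loess scaling. Of 25 hypoxia and glycolysis genes, 10 were at least 2-fold higher and 0 lower by that much (median 0.81, above all 10000 random lists, and 0.42 with spike-in centring). Pdk1 (6.04-fold by the median of 5 probes) and Pfkp (5.61-fold, 5 probes) were the highest, and Hk1 (log2 0.26, or −0.13 with spike-in centring and −0.08 with its brightest probe) and Vegfa (−0.17, with probes from −1.17 to 0.69) the lowest.

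Stress genes were higher in part. Of 18 heat shock and immediate early genes, 8 were at least 2-fold higher and 1 at least 2-fold lower (median 0.96, above all 10000 random lists, and 0.57 with spike-in centring, which left 4 higher and 2 lower); Hspb1 (7.09-fold) and Hspa1b (5.20-fold) led, and Egr2 (4.44-fold) and Jun (log2 −0.72) were lowest. Of 20 p53 and apoptosis genes, 5 were at least 2-fold higher and 0 lower by that much (median 0.73, above all 10000 random lists, and 0.34 with spike-in centring, which left 3 higher), with Gdf15 (5.92-fold) and Pmaip1 (5.28-fold) highest and Btg2 (log2 −0.57) and Zmat3 (−0.04) lowest. The 16 genes of the unfolded protein and amino acid stress list had a median of 0.15 (−0.24 to 0.33 over all settings run), inside the random range, and the 21 cholesterol synthesis genes, all within 2-fold, a median of −0.20, also inside it; with spike-in centring that median was −0.59 and Hmgcs1 (log2 −1.01) passed 2-fold lower. Of 4061 long intergenic RNA loci on the array, 1803 were measured on both arrays; 225 were at least 2-fold higher and 106 at least 2-fold lower, the furthest being a locus on chromosome 17 at 15368546 to 15377747 (mm9, reverse strand, log2 4.47) and a locus on chromosome 16 at 34559623 to 34560462 (reverse strand, −3.09). The medians of genes on each autosome lay within −0.07 and 0.07 of the median of all genes, where 3 copies in place of 2 would give 0.58.

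Naive pluripotency genes were higher and neural genes lower on the knockout array. Scaling by a constant cannot be the whole cause, because it moves both lists alike and cannot bring medians of 3.07 and −2.0 both near 0. Centring on the median or on spike-ins could therefore not have changed this outcome. Background correction is argued against as the whole cause by normexp, which left the neural progenitor median at −1.63, the closest to 0 over 5 other settings. The naive pluripotency median came no closer to 0 than 2.68 over these settings. An intensity trend is argued against in the same way, by a median of −2.05 after loess. Swapped labels of the arrays stay open, because 0 probes name Linc1548 and its locus was not searched by position. Array position and differences between the cultures stay open too. A slower or incomplete exit from pluripotency after loss of Linc1548 is a hypothesis that may account for the pattern, and it was not tested, nor can 1 array per group separate it from a culture that differentiated at another pace.

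The 2-cell-like genes were higher on the knockout array. A single signal of the Zscan4 genes counted several times, through near-identical family members, is argued against as the whole cause, since 5 of the 7 other measured members were at least 2-fold higher (median 3.50, lower quartile 1.22). That median is the value of Zfp42, also a naive pluripotency gene, and without Tcstv3, Usp17la and Gm8300 the 4 members left had a median of 1.22. With normexp background correction and its offset the list median was 3.41. That does not decide whether signal near background on the wild type array raised the folds. Most members read far above the offset on the knockout array, so the median would have stayed high either way. Folds of members near background on the wild type array, such as Gm8300 (23.7) and Usp17la (37.7), stay uncertain. A larger share of cells in a 2-cell-like state in the knockout culture could give the higher 2-cell-like signals. Higher levels in each cell could give them too. Bulk arrays do not separate these, and neither was tested.

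Endogenous signal was lower on the knockout array relative to the spike-in controls, by −0.39 on the log2 scale at the 75th percentile. More degraded RNA on the knockout array predicts relatively lower signal toward the 5' end, and the data went the other way: the difference of 3' probes less that of 5' probes had a median of −0.17. Less RNA in the labelling reaction of the knockout sample could give the −0.39 and stays open, as does a lower share of messenger RNA, since no amount measured per reaction was used here. The shift was uneven across genes. With spike-in centring the median was −0.29 over all genes and −0.03 over 26 ribosomal protein genes, so an even loss alone does not describe it. The −0.17 itself may reflect more degraded RNA on the wild type array or shorter 3' ends of transcripts in the knockout, and neither was tested.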
